A study of Mus musculus with 9 samples.

How the data were processed

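RNA sequencing libraries of mouse plasmacytoid dendritic cells (pDCs) sorted by flow cytometry were compared after treatment with phosphate-buffered saline (PBS, the vehicle), mitochondrial DNA (mtDNA) or oxidized mitochondrial DNA (Ox-mtDNA), with 3 libraries in each of the 3 groups and 9 libraries in all. Per the labels, total RNA was extracted with TRIzol and RNeasy columns, polyadenylated RNA was selected with oligo-T beads, and cDNA was primed with random hexamers. The deposited table held raw counts per gene, with no normalization by the authors. Per the submitters' processing notes, reads were trimmed with fastp 0.23.4, aligned to GRCm39 with STAR 2.7.11b and counted with featureCounts 2.0.1. Per the file headers, featureCounts counted fragments over the exons of each gene of GENCODE M34 without using strand. A fragment that overlapped several genes was counted for each of them, and fragments with several alignments were not counted. Counts of overlapping or antisense genes and of near-identical copies are therefore uncertain.

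The table held 57126 genes, of which 19757 had no count in any library and 51884 were matched to a symbol. Total counts per library ranged from 16029951 to 25378884. Counts of replicates of one group differed by 15.4 to 347 times the variance of counting error (chi-square per degree of freedom), so the differences between replicates, not the depth, set the precision of the fold changes. The labels do not state whether replicates were separate cultures or separate animals, so p-values measure the spread between these samples. Samples were assigned to groups from their titles, and all 9 columns of counts were used.

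Analysis was done in R 4.3.3. Genes were kept with filterByExpr of edgeR 4.0.16 at its minimum count of 10, which left 17555 genes. Libraries were normalized with TMM factors. One model with a coefficient per group was fitted to all 9 libraries (6 residual degrees of freedom) with the robust quasi-likelihood method of edgeR, and the 3 differences between groups were tested with the quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05 and no minimum fold change. Values per library are given as CPM, counts scaled to a common library size with the TMM factors. Standard errors (SE) belong to the log2 fold change of the model, and differences between libraries of the same replicate number are given as log2 CPM differences.

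A set of 32 gene lists with 878 entries (875 matched, 20 of them under another symbol) was written before the data were examined, as were the tests, the rule for naming genes and most of the other settings below. The 23 pathway lists were interferon genes, interferon-stimulated genes, inflammatory cytokines, NF-kB targets, costimulation and maturation, T follicular helper (Tfh) cell help, MHC class II, MHC class I, endosomal Toll-like receptor (TLR) machinery, cytosolic DNA sensing, inflammasome, NRF2 oxidative stress response, base excision repair, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, glycolysis and hypoxia, cell cycle, p53 and apoptosis, unfolded protein response, immediate-early genes, heat shock, cholesterol synthesis and ribosomal proteins. The 9 cell type lists were markers of pDCs, type 1 conventional dendritic cells (cDC1), type 2 conventional dendritic cells (cDC2), monocytes and macrophages, neutrophils, B cells, T cells, natural killer (NK) cells and erythroid cells. Some lists share members, so their calls are not independent. Tfh help overlaps with inflammatory cytokines and with costimulation, and interferon-stimulated genes overlap with cytosolic DNA sensing. The 30 lists with enough measured members were tested with camera of limma 3.58.1, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes. As alternatives, the correlation was estimated for each list, and fry tested each list by itself. Members were also counted after adjustment over the list alone.

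The rule for naming genes took, in a comparison with fewer than 5 genes past the threshold, the 10 with the smallest unadjusted p-values. It added up to 4 members of each list with the smallest adjusted p-values, and in every comparison the genes Ifnb1, Ifna4, Isg15, Ifit1, Mx1, Irf7, Cxcl10, Il6, Tnf, Il12b, Cd40, Cd80, Cd86, Icosl, Tnfsf13b, Tlr9, Sting1, Cgas and Siglech. Ifna4 and Tnfsf13b were not among the tested genes. For comparisons with 5 or more genes past the threshold the rule took the 12 highest and 12 lowest fold changes, which was not needed.

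Other settings written at that time were DESeq2 size factors or upper quartile normalization in edgeR, the Wald test of DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 3 libraries, only the 6 libraries of a comparison, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Settings chosen after seeing the data were replicates 1 and 2 only, a term for replicate 3, a GC correction, limma-voom with a replicate block or with sample quality weights, and combinations of these. GC content came from GENCODE M21 transcripts, an older annotation than that of the counts, and covered 16750 (95.4%) of the tested genes. The GC correction subtracted a lowess trend with a span of 0.2 as an offset. Gene symbols came from a table of gene names.

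The pairing of the replicate numbers was checked from the data, since the labels state none. Deviations from the group means, correlated across genes between libraries of the same number, ranged from 0.487 to 0.897, and 7 of 9 libraries correlated best with a library of their own number. Within replicates 1 and 2 alone the correlations were -0.0821 for Ox-mtDNA and PBS, 0.334 for mtDNA and PBS and 0.0645 for Ox-mtDNA and mtDNA, so most of the pairing lay between replicate 3 and the other replicates. The covariance that the fold changes of Ox-mtDNA and mtDNA against PBS would have without an effect was also computed from these deviations, with and without the correlation of same-numbered libraries.

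The pipeline was tested on simulated data with the spread and depth of these libraries. With 2-fold, 4-fold and 8-fold changes put into 67, 67 and 66 genes, the model of all 9 libraries recovered 0, 0 and 0 of them in Ox-mtDNA against PBS. With the replicate block it recovered 1.49%, 56.7% and 92.4%, and with replicates 1 and 2 only 0%, 49.3% and 75.8%. Unchanged genes called in the same simulations numbered 0, 3 and 5. Camera gave a p of 2.06e-07 for a shifted list of 30 simulated genes and 0.727 for an unshifted list of 30. The simulated genes were drawn independently, so this did not test camera on lists of correlated genes. In the data, the correlation estimated in Ox-mtDNA against PBS ranged from -0.135 for NK cell markers to 0.981 for ribosomal proteins, with 0.486 for heat shock genes. The GC correction reduced a simulated slope of -0.0876 log2 units per percent GC to 0.00299.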

Results

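Gene expression was measured in sorted mouse pDCs, the dendritic cells specialised in type I interferon production, after treatment with PBS, mtDNA or Ox-mtDNA (3 libraries each). Total counts in replicates 1, 2 and 3 were 20999081, 18989748 and 25378884 in PBS. They were 17814132, 17853538 and 18338436 after mtDNA and 16029951, 20734950 and 19302548 after Ox-mtDNA. Siglech, a surface receptor that marks mouse pDCs, was abundant in every group, at 2140 ± 376 CPM (SD, n = 3) in PBS, 1940 ± 226 CPM (SD, n = 3) after mtDNA and 1670 ± 425 CPM (SD, n = 3) after Ox-mtDNA.

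The 3 libraries of replicate 3 stood apart from the other 6 in every group. The first principal component, 70.7% of the variance, separated them, and the second held 13%. Xist, the RNA of the inactive X chromosome, was at 849, 1930 and 2100 CPM in PBS, mtDNA and Ox-mtDNA replicate 3, and at 0 to 0.772 CPM in the other libraries. Genes of the Y chromosome together were at 1.22, 3.16 and 5.54 CPM in the same replicate 3 libraries and at 263 to 349 CPM elsewhere. The 770 genes of more than 60% GC had median log2 differences of -3.27, -2.89 and -2.65 from the mean of PBS replicates 1 and 2. Replicates 1 and 2 also differed from each other within Ox-mtDNA. Their log2 CPM correlated at 0.911, against 0.986 in PBS and 0.987 in mtDNA. Their chi-square per degree of freedom was 165, against 20.9 in PBS and 15.4 in mtDNA. Median log2 differences between libraries of the same number are therefore given for the gene lists called on all 9 libraries.

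**Figure D1:**
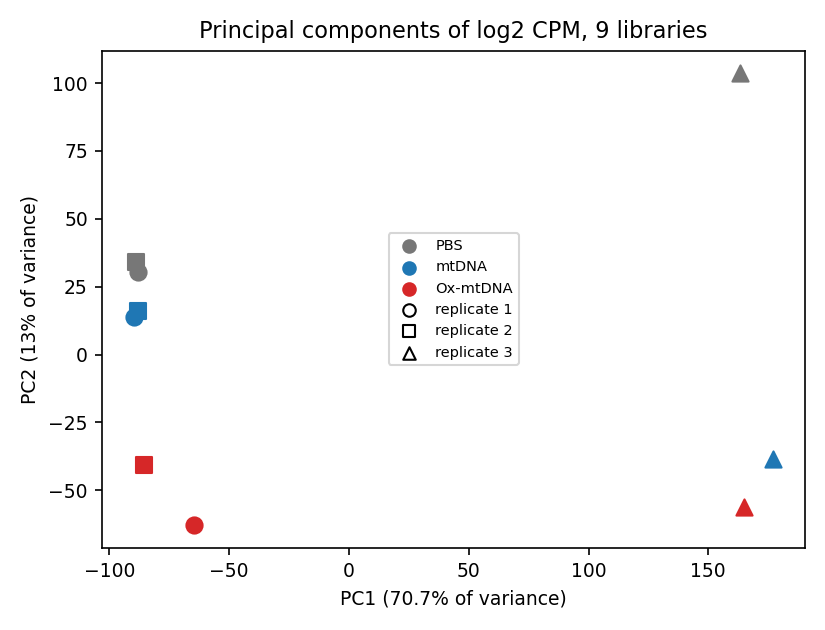
Principal components of log2 CPM for the 9 libraries, coloured by treatment and numbered by replicate. The horizontal axis (70.7% of the variance) separates the 3 libraries of replicate 3 from the other 6, and within replicates 1 and 2 the Ox-mtDNA libraries lie lowest on the vertical axis (13%).

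The comparison of Ox-mtDNA with PBS asked how pDCs respond to oxidized mitochondrial DNA. Heat shock genes, which encode chaperones that fold and protect proteins, rose as a group, and so did immediate-early genes, the transcription factors and signalling genes switched on first after stimulation. Both lists were defined beforehand as also a sign of handling stress, and handling was not tested as a cause. The camera adjusted p was 2.53e-14 for heat shock and 3.64e-17 for immediate-early genes, and both calls were lost at an adjusted p = 0.262 with an estimated correlation. Hspb1, a small heat shock protein (chromosome 5, 135916773 to 135918417, GRCm39), averaged 1.25 ± 1.07 CPM (SD, n = 3) in PBS and 287 ± 251 CPM (SD, n = 3) after Ox-mtDNA, a log2 fold change of 7.85 (SE 1.46), with differences of 8.87, 7.09 and 4.83 in replicates 1, 2 and 3. Its GC content is 61.7%, in the range that was low in every replicate 3 library, so its level there cannot be set against replicates 1 and 2. Hsp90aa1, the inducible cytosolic HSP90 (chromosome 12, 110657039 to 110662829), went from 513 ± 115 to 5260 ± 2800 CPM (SD, n = 3 each), a log2 fold change of 3.36 (SE 0.71), with replicate differences of 4.02, 3.85 and 1.69. Dusp1, a phosphatase that switches off MAP kinases, had a log2 fold change of 5.20 (SE 1.02), from 4.70 to 173 CPM.

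All 19 measured heat shock genes had positive fold changes, with a median of 1.70 on the log2 scale. None passed over all genes, and 11 passed when adjusted over the list alone (edgeR quasi-likelihood). The median heat shock difference was 2.04 in replicate 1, 2.45 in replicate 2 and 0.74 in replicate 3. All 29 immediate-early genes had positive fold changes, with a median of 2.63. Adjusted over the list alone, 12 of them passed, against 0 over all genes, and the replicate medians were 2.05, 2.40 and 2.95. The last rests on a low control. The median level of the list was 0.52 log2 CPM in PBS replicate 3, against 4.34 and 4.16 in PBS replicates 1 and 2. In Ox-mtDNA replicate 3 it was 3.31, below both of the latter. Among their members, Nr4a1, a nuclear receptor induced by stimulation, had a log2 fold change of 5.16 (1267.58, 212.74 and 137.59 CPM in Ox-mtDNA replicates 1, 2 and 3) and Atf3, a stress-induced transcription factor, one of 6.46. Genes of the unfolded protein response rose with a median of 0.15, and 20 of 30 were positive (camera adjusted p = 0.0191, and adjusted p = 0.262 with an estimated correlation). They included Ppp1r15a, which restores translation after stress, at 3.36 and Ddit3, the transcription factor CHOP, at 2.17, and 4 members passed when adjusted over the list alone against 0 over all genes. The replicate medians of the list were 0.24, 0.10 and 0.22, and the call was lost without Ox-mtDNA replicate 1 (adjusted p = 0.0945), PBS replicate 2 (0.132) or Ox-mtDNA replicate 2 (0.0949).

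Interferon-stimulated genes, the antiviral effectors induced by interferon signalling, fell after Ox-mtDNA. Of 64 measured members 57 had negative fold changes, with a median of -0.99 (camera adjusted p = 7.03e-14, and adjusted p = 0.429 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone. The replicate medians were -1.38, -0.95 and -0.98. Ifi47, an interferon-inducible GTPase, had a log2 fold change of -1.31 (SE 0.301), from 174 to 70.3 CPM. Genes of cytosolic DNA sensing, the pathway of cGAS and STING, fell with a median of -0.48, and 17 of 20 were negative (camera adjusted p = 0.00472, and adjusted p = 0.367 with an estimated correlation). The replicate medians were -0.22, -0.51 and -0.54, and Trex1, a DNase that degrades cytosolic DNA, was among them at -1.19. No member passed when adjusted over the list alone. Cgas itself averaged 12.6 ± 7.25 CPM in PBS and 27.6 ± 10.4 CPM after Ox-mtDNA (SD, n = 3 each), a log2 fold change of 1.13 (SE 0.527) that did not pass (adjusted p = 0.541), with replicate differences of 1, 0.08 and 2.75. MHC class II genes fell with a median of -0.26 and MHC class I genes with a median of -0.23 (camera adjusted p = 0.0175 for both). With an estimated correlation the adjusted p = 0.262 for class II and the adjusted p = 0.511 for class I. Replicate medians were -0.19, -0.35 and -0.22 for class II and -0.16, -0.94 and -0.31 for class I. The class I call was lost without PBS replicate 2 (adjusted p = 0.0885) or Ox-mtDNA replicate 3 (adjusted p = 0.149).

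Cholesterol synthesis genes fell, and 23 of 24 had negative fold changes with a median of -0.79 (camera adjusted p = 4.43e-10, and adjusted p = 0.309 with an estimated correlation). Sqle, squalene epoxidase (chromosome 15, 59186930 to 59203041), went from 305 ± 79.2 to 98.6 ± 13.8 CPM (SD, n = 3 each), a log2 fold change of -1.63 (SE 0.308). Acat2, which makes acetoacetyl-CoA at the start of the pathway, had a log2 fold change of -2.13 (SE 0.394). Adjusted over the list alone 3 cholesterol genes passed, all lower, against 0 over all genes, and the replicate medians of -0.49, -1.88 and -0.14 were uneven. pDC identity genes fell with a median of -0.57, and 25 of 29 were negative (camera adjusted p = 9.39e-07, and adjusted p = 0.262 with an estimated correlation). Tlr7, the endosomal receptor for single-stranded RNA, went from 279 ± 57.6 to 105 ± 7.02 CPM (SD, n = 3 each), a log2 fold change of -1.41 (SE 0.27). The pDC list had replicate medians of -0.15, -1.36 and -0.60, and 1 member passed when adjusted over the list alone against 0 over all genes. cDC1 markers fell as well, with a median of -0.92 and 12 of 14 negative (camera adjusted p = 0.000278, and adjusted p = 0.262 with an estimated correlation). By replicate the medians were -0.66, -0.67 and -0.74.

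Inflammatory cytokine genes rose as a group, with 21 of 29 positive and a median of 1.19 (camera adjusted p = 0.000948, and adjusted p = 0.262 with an estimated correlation). Replicate medians were -0.17, 1.38 and 1.48. Ccl4, a chemokine that attracts lymphocytes and monocytes, was at 2.05 to 3.02 CPM in the PBS libraries, and at 604.22, 41.63 and 607.41 CPM in Ox-mtDNA replicates 1, 2 and 3. Mitochondrially encoded genes rose with a median of 0.62 and 13 of 15 positive (camera adjusted p = 0.00037, and adjusted p = 0.528 with an estimated correlation). Medians in replicates 1, 2 and 3 were 1.08, 1.18 and -0.19, and the call was lost without PBS replicate 2 (adjusted p = 0.0747). All 72 ribosomal protein genes were positive with a median of 0.46 (camera adjusted p = 6.01e-06, and adjusted p = 0.755 with an estimated correlation). Their replicate medians were 0.55, 0.56 and 0.36, and the call was lost without PBS replicate 2 (adjusted p = 0.0885) or Ox-mtDNA replicate 3 (adjusted p = 0.518). Fragments with a further alignment, as to a processed pseudogene, were not counted, so the levels of ribosomal protein genes are uncertain.

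No single gene passed the threshold over all genes in Ox-mtDNA against PBS by edgeR without a block. The edgeR quasi-likelihood test of all 9 libraries called 0 of 17555 genes (smallest adjusted p = 0.472), with 1722 at an unadjusted p under 0.05 where 878 would be expected by chance. Another split of the same libraries, PBS replicates 1 and 2 with Ox-mtDNA replicate 2 on one side, gave 1627. Its other side held both replicate 3 libraries of the comparison, so that count also measures how replicate 3 differs. An excess over 878 can thus arise without the treatment. This split does not decide whether the treatment gave the 1722. limma-voom called 0, or 73 with sample quality weights and the replicate block (68 higher and 5 lower), a setting chosen after seeing the data. DESeq2 called 328, of which 251 were higher and 77 lower. The genes with the smallest edgeR p-values included Kctd19, a potassium channel domain protein (chromosome 8, 106109439 to 106140134), at 0.122 ± 0.0802 CPM in PBS and 13.2 ± 12.2 CPM after Ox-mtDNA (SD, n = 3 each), where its replicates were at 3.85, 26.98 and 8.72 CPM. Odc1, the rate-limiting enzyme of polyamine synthesis (chromosome 12, 17594795 to 17601085), went from 86.3 ± 26.2 to 547 ± 117 CPM (SD, n = 3 each), a log2 fold change of 2.66 (SE 0.41). With the replicate number as a block, edgeR called 1 gene, Kctd19 (log2 fold change 6.53, adjusted p = 0.0267), with 3345 at an unadjusted p under 0.05. In replicates 1 and 2 only, a setting chosen after seeing the data, edgeR called 25 genes, all higher, and 0 of them when the replicate block was added (smallest adjusted p = 0.103). Among these 25 were Egr1, an immediate-early transcription factor, at 3.86 (SE 0.235, edgeR adjusted p = 0.0276), Hsp90aa1 at 3.94, Hspb1 at 7.97, Ppp1r15a at 3.29, Dusp1 at 5.05 and the chaperone Hspa8 at 2.08. Egr1 and Hspa8 were named after their values were seen, as is Hspa1a, which was called at 5.96 but shares its reads with the overlapping gene Gm20481 (the same holds for Jund and Gm11175 and for the pair of genes at the Ptp4a1 locus).

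**Figure D2:**
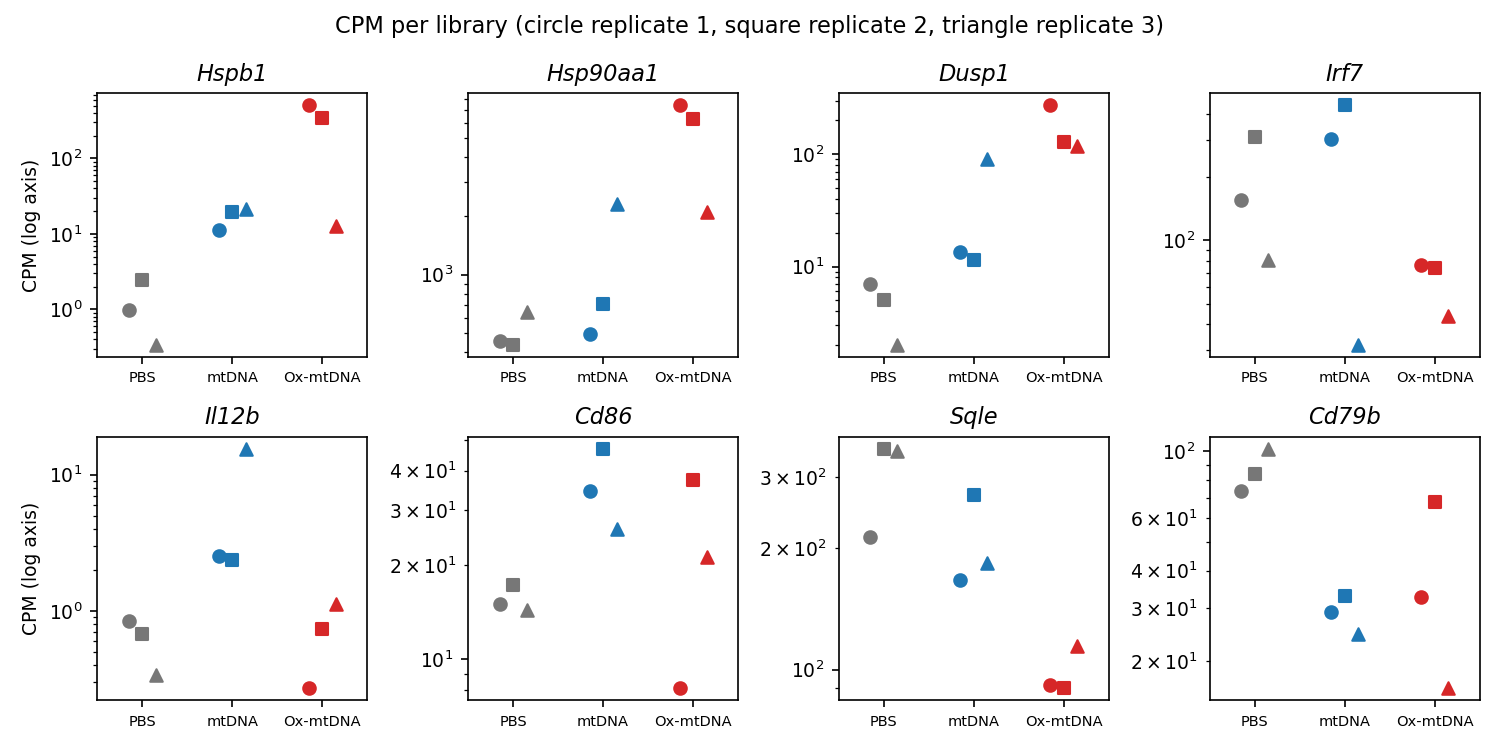
CPM on a logarithmic axis for selected genes in each of the 9 libraries, by treatment, with the replicate marked. Hspb1 was at 503.63, 344.29 and 12.54 CPM in Ox-mtDNA replicates 1, 2 and 3, above the PBS libraries at 0.34 to 2.42 CPM. Its GC content is 61.7%, and genes of such GC content were low in every replicate 3 library.

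The comparison of mtDNA with PBS asked how pDCs respond to mitochondrial DNA that was not oxidized. Inflammatory cytokine genes and genes that help Tfh cells, the T cells that drive antibody responses, rose as groups. The Tfh help list shares members with the cytokine list, such as Il6 and Il12b. It also shares members with the costimulation list, such as Icosl, Cd80 and Cd86, so these calls are not independent. The camera adjusted p was 1.57e-13 for the cytokines and 2.48e-06 for Tfh help, and adjusted p = 0.0479 for each with an estimated correlation. With the replicate block and an estimated correlation both calls were lost, at adjusted p = 0.347. Il12b, a subunit of interleukin-12 (chromosome 11, 44290890 to 44304860), averaged 0.616 ± 0.252 CPM (SD, n = 3) in PBS and 6.77 ± 7.51 CPM (SD, n = 3) after mtDNA, a log2 fold change of 3.45 (SE 0.933). The mtDNA replicates were at 2.51, 2.37 and 15.44 CPM, and in replicates 1 and 2 only the log2 fold change was 1.68 (SE 0.544). Cxcl10, a chemokine that attracts activated T cells, went from 8.98 ± 8.25 to 52.9 ± 26.6 CPM (SD, n = 3 each), a log2 fold change of 2.56 (SE 0.724), with replicate differences of 1.85, 2.42 and 3.96. Cd86, a costimulatory ligand for CD28, went from 15.5 ± 1.49 to 35.8 ± 10.5 CPM (SD, n = 3 each), a log2 fold change of 1.20 (SE 0.515).

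Of 29 measured inflammatory cytokine genes 28 had positive fold changes after mtDNA, with a median of 1.11. Of 18 Tfh help genes 16 were positive, with a median of 0.92. With an estimated correlation in replicates 1 and 2 only, both lists were at an adjusted p = 0.294, and by fry on all 9 libraries at an adjusted p = 0.108. The medians in replicates 1, 2 and 3 were 0.65, 0.89 and 1.78 for the cytokines and 0.61, 0.91 and 1 for Tfh help. Costimulation and maturation genes rose with 22 of 26 positive and a median of 0.81 (camera adjusted p = 8.05e-06, and adjusted p = 0.11 with an estimated correlation). Cd83, a surface marker of mature dendritic cells, had a log2 fold change of 2.80 (SE 0.696) and one of 1.39 (SE 0.235) in replicates 1 and 2 only, and Cd80, the other CD28 ligand, had one of 1.52. The replicate medians of this list were 0.65, 0.71 and 0.88. NF-kB targets rose with 29 of 32 positive and a median of 0.59 (camera adjusted p = 2.51e-05, and adjusted p = 0.418 with an estimated correlation). Immediate-early genes rose with 24 of 29 positive and a median of 0.99 (camera adjusted p = 1.03e-07, and adjusted p = 0.394 with an estimated correlation). Replicate medians were 0.48, 0.40 and 1.20 for NF-kB targets and 0.45, 0.40 and 2.97 for immediate-early genes. The 2.97 rests on PBS replicate 3, where immediate-early genes were at a median of 0.52 log2 CPM, against 4.34 and 4.16 in PBS replicates 1 and 2. Without PBS replicate 3 both calls were lost, at adjusted p = 0.147 for NF-kB targets and adjusted p = 0.174 for immediate-early genes.

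Interferon-stimulated genes differed between replicates after mtDNA. Of 64 members 59 had positive fold changes with a median of 0.55 (camera adjusted p = 0.00718, and adjusted p = 0.889 with an estimated correlation), and the replicate medians were 0.74, 0.75 and -1.05. Rsad2, the antiviral protein viperin, had a log2 fold change of 1.57. The call did not hold with the replicate block (adjusted p = 0.0657). It was lost without PBS replicate 1 (adjusted p = 0.0534), mtDNA replicate 1 (adjusted p = 0.856) or PBS replicate 3 (adjusted p = 0.438), and the direction turned without mtDNA replicate 2 (adjusted p = 0.149). With replicates 1 and 2 only, chosen after seeing the data, the camera adjusted p was 4.34e-26. That call was lost as well, at an adjusted p = 0.294 with an estimated correlation and an adjusted p = 0.489 by fry.

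B cell markers fell after mtDNA, with all 16 members negative and a median of -0.61 (camera adjusted p = 3.05e-07, and adjusted p = 0.332 with an estimated correlation). Medians in replicates 1, 2 and 3 were -0.49, -1.01 and -0.35. Cd79b, a signalling chain of the B cell receptor (chromosome 11, 106202167 to 106205588), went from 86.6 ± 14.3 to 28.9 ± 4.16 CPM (SD, n = 3 each), a log2 fold change of -1.58 (SE 0.48). Nuclear oxidative phosphorylation genes fell by a small amount, with 71 of 75 negative and a median of -0.19 (camera adjusted p = 0.000134, and adjusted p = 0.889 with an estimated correlation). Replicate medians were -0.10, -0.07 and -0.31. The call was lost without mtDNA replicate 1 (adjusted p = 0.0749), and the direction turned without PBS replicate 3 (adjusted p = 0.447). pDC identity genes fell with a median of -0.26 (camera adjusted p = 0.000362, and adjusted p = 0.422 with an estimated correlation), with replicate medians of -0.18, -0.18 and -0.52, a call lost without mtDNA replicate 3 (adjusted p = 0.076). Cholesterol synthesis genes fell with a median of -0.28 (camera adjusted p = 0.000802, and adjusted p = 0.723 with an estimated correlation). By replicate the medians were -0.20, -0.46 and 0.06, and the call was lost without mtDNA replicate 1 (adjusted p = 0.173) or PBS replicate 2 (adjusted p = 0.188). cDC1 markers fell with a median of -0.23 (camera adjusted p = 0.022, and adjusted p = 0.422 with an estimated correlation). Their replicate medians were -0.06, -0.17 and -0.93, and they lost the call without PBS replicate 3 (adjusted p = 0.174) or mtDNA replicate 3 (adjusted p = 0.547). The camera direction turned in replicates 1 and 2 only (adjusted p = 0.879).

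No single gene passed in mtDNA against PBS by edgeR (smallest adjusted p = 1, with 460 genes at an unadjusted p under 0.05), nor by limma-voom, and no member of any list passed when adjusted over the list alone. The 460 lay below the 878 expected by chance, and with the replicate block 998 genes were at an unadjusted p under 0.05, again with 0 past the threshold (smallest adjusted p = 0.174). limma-voom with sample quality weights and the block, chosen after seeing the data, gave a very different count of 712 genes, 468 higher and 244 lower. DESeq2 called 10 genes, all higher. Among these 10 were Kctd19 at 4.97 (DESeq2 adjusted p = 0.00197), Odc1 at 2.21 (DESeq2 adjusted p = 0.0151) and Slc16a6, a transporter of the monocarboxylate family, at 3.35 (DESeq2 adjusted p = 0.0151). With replicates 1 and 2 only, edgeR called 0 genes, with 450 at an unadjusted p under 0.05.

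The comparison of Ox-mtDNA with mtDNA asked what the oxidation of the DNA changed. Interferon-stimulated genes fell together, and heat shock, immediate-early and mitochondrially encoded genes rose. With an estimated correlation these camera calls were lost, at adjusted p = 0.162 for the first 3 lists and adjusted p = 0.182 for the mitochondrially encoded genes, and in replicate 3 their medians were 0.06, 0.00, 0.23 and -0.06. Irf7, the transcription factor that drives interferon-alpha genes in pDCs (chromosome 7, 140842619 to 140846394), averaged 257 ± 206 CPM (SD, n = 3) after mtDNA and 64.5 ± 18.2 CPM (SD, n = 3) after Ox-mtDNA, a log2 fold change of -2.00 (SE 0.867). Its replicate differences were -1.99 and -2.57 in replicates 1 and 2 and 0.45 in replicate 3, where it was at 31.92 CPM after mtDNA and 43.49 CPM after Ox-mtDNA. Itga4, the integrin alpha 4 chain (chromosome 2, 79085844 to 79163467), went from 336 ± 65.7 to 145 ± 21.7 CPM (SD, n = 3 each), a log2 fold change of -1.22 (SE 0.243), with replicate differences of -1.52, -1.47 and -0.63. Hspb1 had a log2 fold change of 4.05 in this comparison, with replicate differences of 5.45, 4.15 and -0.75.

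All 64 interferon-stimulated genes had negative fold changes, with a median of -1.62 (camera adjusted p = 3.44e-42, and adjusted p = 0.162 with an estimated correlation). The replicate medians were -2.11, -1.73 and 0.06, and 0 members passed over all genes or when adjusted over the list alone. Gbp7, an interferon-inducible GTPase, had a log2 fold change of -2.12, Isg15, a ubiquitin-like antiviral modifier, one of -2.02 and Mx1, an antiviral GTPase, one of -1.38. Their differences in replicate 3 were 0.06, -0.31 and 0.11. Cytosolic DNA sensing genes fell with 15 of 20 negative and a median of -0.35 (camera adjusted p = 3.63e-05, and adjusted p = 0.162 with an estimated correlation), and the replicate medians were -0.52, -0.81 and 0.11. All 19 heat shock genes were positive with a median of 1.67 (camera adjusted p = 8.07e-25, and adjusted p = 0.162 with an estimated correlation), and 10 passed when adjusted over the list alone against 0 over all genes. By replicate the medians were 1.93, 2.27 and 0.00. Against PBS the heat shock medians in replicate 3 were 0.76 after mtDNA and 0.74 after Ox-mtDNA. Hsp90ab1, the constitutive cytosolic HSP90, had a log2 fold change of 1.37 (SE 0.388), with replicate differences of 1.93, 2.08 and 0.04. All 29 immediate-early genes were positive with a median of 1.53 (camera adjusted p = 6.63e-16, and adjusted p = 0.162 with an estimated correlation), and the replicate medians were 2.11, 2.03 and 0.23. All 15 mitochondrially encoded genes were positive with a median of 0.81 (camera adjusted p = 1.7e-13, and adjusted p = 0.182 with an estimated correlation), and the replicate medians were 1.20, 1.29 and -0.06.

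**Figure D3:**
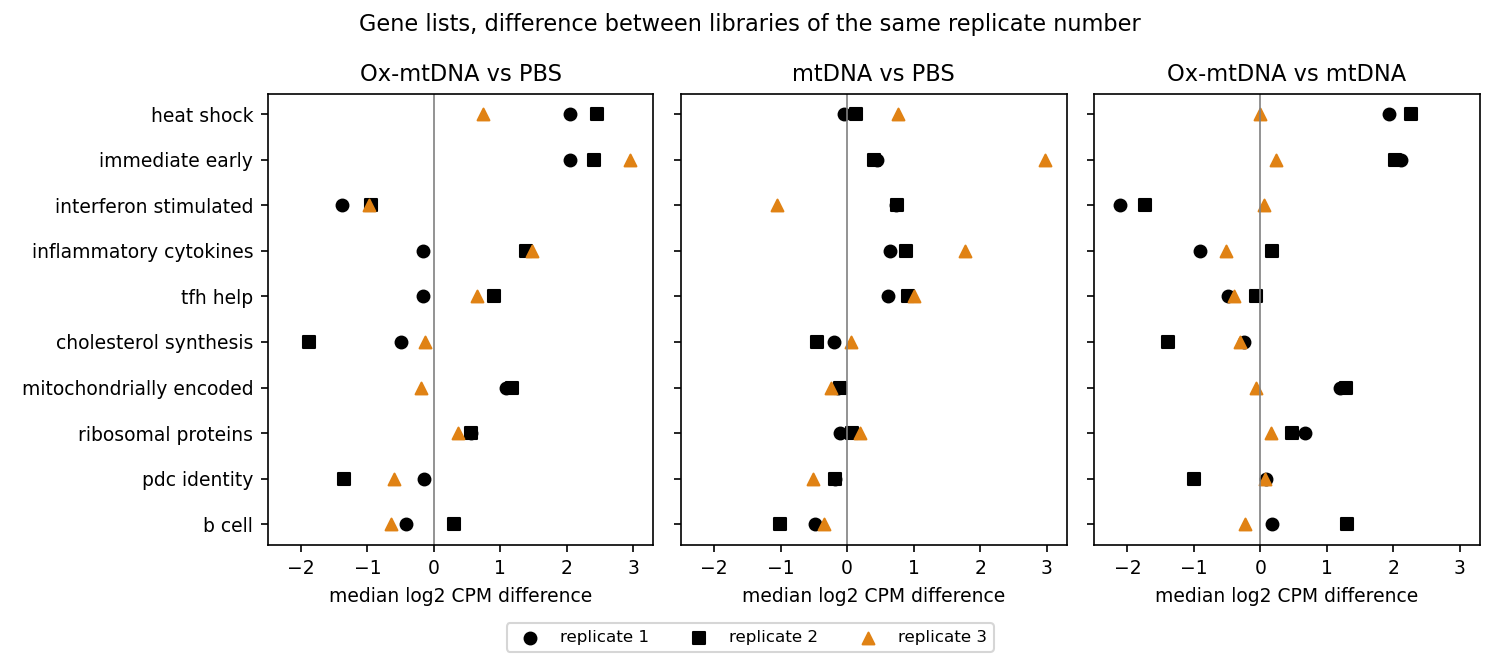
Median log2 CPM difference of selected gene lists between libraries of the same replicate number, in the 3 comparisons, with a symbol for each replicate. Between Ox-mtDNA and mtDNA the interferon-stimulated genes lie at -2.11 and -1.73 in replicates 1 and 2 and at 0.06 in replicate 3, and heat shock genes at 1.93, 2.27 and 0.00.

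Cholesterol synthesis genes were lower after Ox-mtDNA than after mtDNA, all 24 of them, with a median of -0.57 (camera adjusted p = 5.13e-09, and adjusted p = 0.231 with an estimated correlation). Medians in replicates 1, 2 and 3 were -0.24, -1.39 and -0.30. Costimulation genes fell with a median of -0.41 (camera adjusted p = 0.000469) and Tfh help genes with a median of -0.44 (camera adjusted p = 0.00461), each with an adjusted p = 0.162 with an estimated correlation. Replicate medians were -1.09, 0.21 and -0.61 for costimulation and -0.49, -0.06 and -0.40 for Tfh help. These lists share members, among them Icosl, so the calls are not independent. Icosl, the ligand through which dendritic cells and B cells support Tfh cells, went from 67.2 ± 6.07 to 32.6 ± 7.54 CPM (SD, n = 3 each), a log2 fold change of -1.04 (SE 0.267). Il12b had a log2 fold change of -3.22 (SE 0.925), and one of -2.22 (SE 0.569) in replicates 1 and 2 only. Without Ox-mtDNA replicate 1 both calls were lost, at adjusted p = 0.101 for costimulation and adjusted p = 0.155 for Tfh help, and so they were without mtDNA replicate 3, at adjusted p = 0.0574 and adjusted p = 0.455. In replicates 1 and 2 only they did not pass either (adjusted p = 0.168 and adjusted p = 0.539). Inflammatory cytokine genes fell with a median of -0.23 and NF-kB targets with a median of -0.10 (camera adjusted p = 0.0152 for both). With an estimated correlation the adjusted p = 0.301 for the cytokines and the adjusted p = 0.47 for the NF-kB targets. Replicate medians were -0.91, 0.17 and -0.51 for the cytokines and -0.61, 0.44 and -0.45 for the NF-kB targets. The cytokine call was lost without Ox-mtDNA replicate 1 (adjusted p = 0.155) or replicate 3 (adjusted p = 0.083), and the direction turned without mtDNA replicate 3 (adjusted p = 0.882). The NF-kB call was lost without Ox-mtDNA replicate 1 (adjusted p = 0.155), Ox-mtDNA replicate 3 (adjusted p = 0.708) or mtDNA replicate 3 (adjusted p = 0.121). Neither passed in replicates 1 and 2 only (adjusted p = 0.68 for the cytokines and adjusted p = 0.985 for the NF-kB targets), and the medians were positive at 0.14 and 0.06.

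pDC identity genes fell with 24 of 29 negative and a median of -0.29 (camera adjusted p = 0.000469, and adjusted p = 0.301 with an estimated correlation). Their replicate medians were 0.09, -1 and 0.07, and the call was lost without Ox-mtDNA replicate 2 (adjusted p = 0.31). MHC class I genes fell with a median of -0.35 (camera adjusted p = 0.0023, and adjusted p = 0.302 with an estimated correlation), with replicate medians of -0.24, -0.98 and 0.09, a call lost without mtDNA replicate 2 (adjusted p = 0.228) or Ox-mtDNA replicate 3 (adjusted p = 0.125). MHC class II genes fell with a median of -0.17 (camera adjusted p = 0.0152, and adjusted p = 0.182 with an estimated correlation). Medians in replicates 1, 2 and 3 were -0.09, -0.51 and -0.08, and the call was lost without Ox-mtDNA replicate 1 (adjusted p = 0.065) or 2 (adjusted p = 0.0537) and without mtDNA replicate 2 (adjusted p = 0.124) or 3 (adjusted p = 0.114). Ribosomal protein genes, all 72 positive, rose with a median of 0.37 (camera adjusted p = 6.66e-10, and adjusted p = 0.482 with an estimated correlation), with replicate medians of 0.67, 0.47 and 0.16, a call lost without Ox-mtDNA replicate 3 (adjusted p = 0.492). Glycolysis and hypoxia genes rose with a median of 0.38 (camera adjusted p = 0.00319, and adjusted p = 0.162 with an estimated correlation), with replicate medians of 0.40, 0.50 and 0.14, a call lost without Ox-mtDNA replicate 2 (adjusted p = 0.0915). Unfolded protein response genes rose with a median of 0.17 (camera adjusted p = 0.0387, and adjusted p = 0.162 with an estimated correlation). By replicate the medians were 0.19, 0.00 and 0.02, and the call was lost when any of 6 libraries was left out: mtDNA replicate 1 (0.0777), Ox-mtDNA replicate 1 (0.155), PBS replicate 2 (0.0575), mtDNA replicate 2 (0.116), Ox-mtDNA replicate 2 (0.213) or PBS replicate 3 (0.054).

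No single gene passed in Ox-mtDNA against mtDNA by edgeR (smallest adjusted p = 1, with 422 at an unadjusted p under 0.05), and limma-voom and DESeq2 called 0 as well. The 422 lay below the 878 expected by chance, and with the replicate block 1195 genes were at an unadjusted p under 0.05, again with 0 past the threshold (smallest adjusted p = 0.405). limma-voom with sample quality weights and the block, chosen after seeing the data, called 3 genes, 2 higher and 1 lower. With replicates 1 and 2 only edgeR also called 0, with a smallest adjusted p = 0.0532 and 2577 genes at an unadjusted p under 0.05. Endosomal TLR machinery, at an adjusted p = 0.0512 by camera, passed with the replicate block (adjusted p = 0.0472) and with DESeq2 size factors (adjusted p = 0.0478). It did not pass with an estimated correlation (adjusted p = 0.302, and 0.272 with the block) or by fry (adjusted p = 0.62). It also passed without PBS replicate 1 (adjusted p = 0.0404), 2 (0.0407) or 3 (0.0416), Ox-mtDNA replicate 2 (0.0146) or mtDNA replicate 3 (0.0175). Of its 32 measured members 18 were negative, with a median of -0.02 and replicate medians of -0.21, -0.19 and 0.06.

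The interferon genes themselves were sparse, and 2 of the 20 listed were among the tested genes, so the list was not tested. Ifnb1, interferon beta (chromosome 4, 88440262 to 88441011), was at 0.05, 0 and 0 CPM in PBS replicates 1, 2 and 3, at 0.32, 0 and 48.93 CPM after mtDNA and at 7.16, 0.26 and 35.18 CPM after Ox-mtDNA. Ifna2, an interferon-alpha gene, had no counts in PBS and averaged 0.816 ± 1.41 CPM (SD, n = 3) after mtDNA and 1.10 ± 0.912 CPM (SD, n = 3) after Ox-mtDNA. In both treated groups Ifnb1 was highest in replicate 3, where interferon-stimulated genes were lower after mtDNA than in PBS.

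The fold changes of Ox-mtDNA and of mtDNA against PBS were compared with each other, since both used the same PBS libraries. They correlated at 0.816 across 17555 genes, which are not independent replicates, against 0.502 in 10 simulations of unchanged groups sharing those libraries. The covariance was 0.666 against 0.418 in the simulations, and 74.2% of genes had the same sign against 66.7%. No gene passed the edgeR threshold in both comparisons, where independent lists would share n1 × n2 / N = 0 and the simulations gave 0. Since 0 genes were called in each comparison, this overlap could only be 0 and carries no information. With 3 PBS libraries the controls could not be split, so part of the excess of the correlation and covariance over 0 may come from the shared controls. The simulated libraries were independent, whereas deviations of same-numbered libraries correlated here, at 0.897 between mtDNA and Ox-mtDNA replicate 3 and at 0.834 between each of them and PBS replicate 3. For differences of mean log2 CPM, a comparison added after seeing the data, the covariance was 0.366. Without an effect, the deviations of the libraries would give 0.479 if the libraries were independent and 0.118 with same-numbered libraries correlated as they were. The correlation of these differences was 0.767, against 0.534 without an effect in the correlated libraries. With same-numbered libraries correlated, both observed values thus lay above those without an effect. The spread of the values without an effect was not computed, so the size of a shared effect is left open.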

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

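The tests with replicates 1 and 2 only, with a term for replicate 3, with a GC correction, with sample quality weights, and with a block in limma-voom or in the list tests with estimated correlation were chosen only after the result was seen. Against 0 genes in each comparison by edgeR, DESeq2 called 328, 10 and 0 genes in Ox-mtDNA against PBS, mtDNA against PBS and Ox-mtDNA against mtDNA. Of the 328, 300 were tested in edgeR and 299 had an unadjusted edgeR p under 0.05. With the replicate block edgeR called 1, 0 and 0 genes, and with the block and a GC correction 1, 0 and 0. Using replicates 1 and 2 only it called 25, 0 and 0, of which 14 were among the 328. limma-voom with sample quality weights and the block called 73, 712 and 3, with weights from 0.157 for Ox-mtDNA replicate 2 to 3.9 for mtDNA replicate 2. The 5 lower genes among the 73 were Sdc3, Gm10392, Sqle, Enpp4 and Stard4, and the 3 were Fosb and Gm20481, higher, and Sdc3, lower. Of these, Sdc3, Gm10392, Enpp4 and Gm20481 were named after their values were seen. Every other setting, including each library left out in turn, gave 0 genes. In the simulation the model of all 9 libraries without a block recovered none of the changed genes, so a count of 0 from that model does not show that no gene changed. Camera called 13, 11 and 19 lists. With an estimated correlation 0, 2 and 0 lists passed, with fry 0, 0 and 0, and with the block and an estimated correlation 0, 0 and 0. In replicates 1 and 2 only it was 0, 0 and 0 with an estimated correlation and 6, 0 and 8 with fry. Leaving out a library gave 11 to 18, 8 to 15 and 15 to 20 lists. The cause of these shifts was not tested. With the block in replicates 1 and 2 only, edgeR called 0 genes, and with the block and an estimated correlation the cytokine and Tfh help calls after mtDNA were lost. The replicate block changed no other call but those of Kctd19, of the interferon-stimulated genes after mtDNA and of endosomal TLR machinery in Ox-mtDNA against mtDNA. Of the values of named genes under other settings 1870 kept their side of the threshold and 46 came to pass it. Of the values of lists 872 kept their direction and side of the threshold, 251 were weaker, 53 stronger and 14 reversed.

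The reversed lists are given as adjusted p-values from camera that carry a minus sign where the list was lower, unless written as adjusted p, and the cause was not tested. Over the left-out libraries, NRF2 genes in Ox-mtDNA against PBS ran from -0.00444 (without Ox-mtDNA replicate 2) to 0.427, and passed as higher without Ox-mtDNA replicate 1 (0.00733) or 3 (0.00751). In Ox-mtDNA against mtDNA they ran from -4.06e-05 (without Ox-mtDNA replicate 2) to 0.882, and passed as higher without Ox-mtDNA replicate 1 (3.49e-05) or 3 (0.00182) or mtDNA replicate 1 (0.0127) or 2 (0.0247). After mtDNA against PBS, interferon-stimulated genes ran from -0.149 (without mtDNA replicate 2) to 0.856 and oxidative phosphorylation genes from -0.0749 to 0.447 (without PBS replicate 3). Ribosomal proteins ran from -0.923 to 0.9, and passed as lower without PBS replicate 2 (-0.0114) or mtDNA replicate 3 (-5.56e-09), and as higher without PBS replicate 3 (6.28e-08) or mtDNA replicate 1 (0.0133) or 2 (0.0262). Between Ox-mtDNA and mtDNA, inflammatory cytokines ran from -0.155 to 0.882 (without mtDNA replicate 3) and B cell markers from -0.644 (without Ox-mtDNA replicate 2) to 0.173. Oxidative phosphorylation genes ran from -0.755 to 0.357, and passed as lower without Ox-mtDNA replicate 3 (-0.0143) and as higher without Ox-mtDNA replicate 2 (0.000145) or mtDNA replicate 3 (0.00944). Cell cycle genes ran from -0.489 to 0.191, and passed as higher without Ox-mtDNA replicate 2 (0.000115) and as lower without Ox-mtDNA replicate 1 (adjusted p = 0.0462) or 3 (adjusted p = 0.00294) or mtDNA replicate 2 (adjusted p = 0.0247). In replicates 1 and 2 only, MHC class I genes after mtDNA were at 0.0317, against an adjusted p = 0.0262 as lower without mtDNA replicate 2, and cDC1 markers at 0.879, at 0.931 with an estimated correlation and at 0.652 by fry.

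Other lists without a call on all 9 libraries in a comparison also came to pass camera there. Those named here passed in a single direction in that comparison, except for the NRF2 genes. Lists that passed in both directions, such as ribosomal proteins after mtDNA, are given above. In Ox-mtDNA against PBS, oxidative phosphorylation genes were lower when any of 5 libraries was left out (adjusted p from 8.29e-06 to 0.0435), B cell markers lower without Ox-mtDNA replicate 2 (0.000278), endosomal TLR machinery lower without Ox-mtDNA replicate 2 (0.0274) or PBS replicate 3 (0.0284), neutrophil markers higher without PBS replicate 3 (0.0243) and NF-kB targets higher without Ox-mtDNA replicate 3 (0.0216). After mtDNA, mitochondrially encoded genes were lower without PBS replicate 1 (0.00593) or 2 (0.000794) or mtDNA replicate 3 (2.25e-05), neutrophil markers lower without PBS replicate 2 (0.000282) or mtDNA replicate 3 (0.00449), and heat shock genes higher without mtDNA replicate 1 (0.0492) or Ox-mtDNA replicate 3 (0.0106). In replicates 1 and 2 only, NRF2 genes (0.033), NF-kB targets (0.0356) and glycolysis and hypoxia genes (0.00496) were higher in Ox-mtDNA against PBS, and the inflammasome (0.00943) and cytosolic DNA sensing (0.0204) after mtDNA, and 0 of these passed with an estimated correlation.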

Other observations

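The tests of Xist and Y-chromosome transcripts, of a separate preparation or animals of another sex or background, of an equal heat shock effect in every replicate, of mitochondrial genes of at least 100 CPM and of carry-over from any added mtDNA were chosen only after the result was seen. Among gene groups not described in the report, markers of neutrophils were higher after Ox-mtDNA than after mtDNA, with 8 of 9 positive and a median log2 fold change of 0.88 (camera adjusted p = 0.0023, and adjusted p = 0.301 with an estimated correlation). Their replicate medians were 1.12, 1.29 and 0.08, and the call was lost without mtDNA replicate 2 (adjusted p = 0.19) or Ox-mtDNA replicate 3 (adjusted p = 0.102). Mpo, the myeloperoxidase of neutrophil granules, had a log2 fold change of 1.06 (SE 0.656). B cell markers were higher in the same comparison, with 13 of 16 positive and a median of 0.41 (camera adjusted p = 0.0152, and adjusted p = 0.425 with an estimated correlation). Cd79a, the partner of Cd79b in the B cell receptor, was at 63.6, 182.22 and 35.6 CPM in Ox-mtDNA replicates 1, 2 and 3. The replicate medians of the B cell markers were 0.18, 1.30 and -0.23. The B cell call was lost without mtDNA replicate 2 (adjusted p = 0.173) or replicate 3 (adjusted p = 0.0612), and the direction turned without Ox-mtDNA replicate 2 (adjusted p = 0.644). cDC1 markers fell, with 11 of 14 negative and a median of -0.48 (camera adjusted p = 0.00461, and adjusted p = 0.231 with an estimated correlation). Their replicate medians were -0.84, -1.02 and 0.39, and the call was lost without mtDNA replicate 2 (adjusted p = 0.0501) or Ox-mtDNA replicate 2 (adjusted p = 0.133).

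NRF2 target genes, which answer oxidative stress, differed between the Ox-mtDNA libraries. Their median difference from PBS was -0.89 in replicate 1, 1.79 in replicate 2 and -0.26 in replicate 3 (camera adjusted p = 0.18). Hmox1, heme oxygenase 1, was 2.08, 5.65 and 0.65 log2 units above PBS in these replicates, and Slc7a11, the cystine transporter subunit, was at -3.21, 6.56 and -0.48. Several lists had no call in any comparison on all 9 libraries, and their camera adjusted p-values follow in the order Ox-mtDNA against PBS, mtDNA against PBS and Ox-mtDNA against mtDNA. They were 0.18, 0.764 and 0.0614 for NRF2 targets, 0.923, 0.0845 and 0.0801 for the inflammasome, 0.58, 0.764 and 0.569 for base excision repair, and 0.653, 0.246 and 0.569 for the cell cycle. For p53 and apoptosis they were 0.917, 0.996 and 0.933, for cDC2 markers 0.24, 0.246 and 0.635, and for monocytes and macrophages 0.689, 0.668 and 0.989. T cell markers had 0.103, 0.308 and 0.139 and NK cell markers 0.782, 0.764 and 0.948. Of the erythroid markers 1 was measured, so that list was not tested.

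Leaving out 1 library gave calls for some of these lists by camera at the preset correlation, and their cause was not tested. p53 and apoptosis genes were lower without Ox-mtDNA replicate 2 against PBS (adjusted p = 0.0101) and against mtDNA (adjusted p = 0.00045). T cell markers were higher without Ox-mtDNA replicate 1 in the same comparisons (adjusted p = 0.0232 and adjusted p = 0.0194). In Ox-mtDNA against PBS, cell cycle genes were higher without Ox-mtDNA replicate 2 (adjusted p = 0.000168) and cDC2 markers lower without Ox-mtDNA replicate 1 (adjusted p = 0.0389). After mtDNA against PBS, markers of monocytes and macrophages were lower without PBS replicate 2 (adjusted p = 0.0186) and cell cycle genes higher without PBS replicate 3 (adjusted p = 0.0043). Inflammasome genes were lower in Ox-mtDNA against mtDNA without mtDNA replicate 1 (adjusted p = 0.0317). The cell cycle and NRF2 lists were called in both directions between Ox-mtDNA and mtDNA, depending on the library left out, and the NRF2 list also between Ox-mtDNA and PBS.

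The median and the camera direction of a list differed in sign in some cases, none of them past the threshold. In Ox-mtDNA against PBS these were base excision repair (median 0.05), p53 and apoptosis (0.17), monocytes and macrophages (0.25) and B cells (0.02), all lower by camera, and neutrophils (-0.37), higher by camera. After mtDNA they were MHC class I (0.12) and endosomal TLR machinery (0.02), lower by camera, and p53 and apoptosis (-0.08), higher by camera. In Ox-mtDNA against mtDNA they were base excision repair (0.03), p53 and apoptosis (0.21) and cDC2 (0.16), all lower by camera.

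The libraries of replicate 3 stood apart from replicates 1 and 2 in all 3 groups. Without genes of the X and Y chromosomes the median correlation across was 0.768, below the lowest of 0.911 between replicate 1 and 2 libraries, which argues against sex-linked transcripts as the whole difference. Xist was at 849 CPM or more in replicate 3 and at 0.772 or less elsewhere, and Y-chromosome genes were at 5.54 CPM or less in replicate 3 and at 263 or more elsewhere. Neither the GC trend nor a separate preparation of cells of one sex gives such values, and animals of another sex in replicate 3 would, which remains a hypothesis for these transcripts since it was found on the same data. For the rest, among 4450 genes of 45 to 50% GC the median correlation across of 0.861 lay below the lowest within of 0.913 while its highest, 0.918, did not, which leaves the GC trend open. Deviations correlated at 0.834 or more between the replicate 3 libraries, so a separate preparation, or the sex or background of the animals, may account for the rest of the difference, and these cannot be told apart there because each covers the same 3 libraries. The labels give neither sex nor preparation.

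Heat shock genes were higher in Ox-mtDNA replicates 1 and 2 than in the matching mtDNA libraries, and in replicate 3 their median difference was 0.00 with quartiles of -0.14 and 0.08. Against PBS their replicate 3 medians were 0.76 after mtDNA and 0.74 after Ox-mtDNA, while the mtDNA medians in replicates 1 and 2 were -0.04 and 0.14. The 0.00 thus reflects like values after both DNAs, not heat shock genes at the PBS level. The GC trend would shift these 19 genes by a median of -0.0344 and any member by 0.087 at most, which argues against it as the cause. One and the same effect of Ox-mtDNA in every replicate stays open, since replicate 3 has 1 library per group and its own spread is unknown. A response of pDCs to Ox-mtDNA that depends on the animals or the culture is a hypothesis that these data leave open. Handling stress, of which these genes are also a sign, was not tested and is left open too.

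Mitochondrially encoded genes were higher in Ox-mtDNA replicates 1 and 2, and DNA from the treatment carried into the libraries is a candidate source. After mtDNA that was not oxidized the higher of the 2 median differences from PBS was -0.11, which argues against carry-over from any added mtDNA, though not against carry-over of the oxidized preparation alone. Evenly counted DNA should add alike per base, and the gene with the highest added CPM per kb was at 13.7 times the median of the 15 genes. That test decides nothing, because mt-Atp6, mt-Co2 and mt-Co3 were under 30 CPM in every library, which uneven alignment gives by itself. Among the 9 genes of at least 100 CPM the ratio was 6.27, between the limits set for even and for uneven addition, so it is open as well. A response of the cells was not told apart from carry-over of oxidized DNA.

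Splits of the 6 libraries of a comparison into 3 against 3 number 10, too few for a share under 0.05. For genes called by edgeR, all 10 of 10 splits gave as many as the real 0 in each comparison, which any split must, so this decides nothing. The highest other count was 0 for Ox-mtDNA against PBS, 0 for mtDNA against PBS and 481 for Ox-mtDNA against mtDNA. The split with 481 put mtDNA replicates 1 and 2 with Ox-mtDNA replicate 2, which points to a structure of the samples other than treatment. For lists called by camera, 2 of 10 splits gave as many as the real 13 in Ox-mtDNA against PBS (highest other 13), 5 of 10 as many as the real 11 after mtDNA (highest other 15) and 1 of 10 as many as the real 19 in Ox-mtDNA against mtDNA (highest other 14). With the replicate block, 1 of the 4 splits that part all 3 pairs gave as many as the real 1 gene, with 0 in the highest other.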
